A study of Folsomia candida with 32 samples.

How the data were processed

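Gene expression was measured in the springtail Folsomia candida, a small soil arthropod, with Agilent arrays that take 2 RNA samples at once, labelled with the dyes Cy3 and Cy5. Per the labels, about 10 animals, 23 days old, were kept for 4 days at 20 °C in jars holding about 25 g of soil, and labelled cRNA was made from 500 ng of total RNA. The labels give the number of animals per jar as 10 in the exposure protocol and as about 30 in the RNA protocol, and which of these applies was not settled. The exposures were LUFA soil, a standard reference soil, with an extract of the Vlagheide soil added, or with the Vlagheide soil itself. Each was given at the no-observed-effect concentration (NOEC) and at the concentration giving a half-maximal effect (EC50). The controls were LUFA soil treated with acetone for the extract and plain LUFA soil for the whole soil.

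The 32 samples lie on 16 arrays, and each array holds 1 exposed and 1 control sample, known from the array named in the labels of each sample. The exposed sample was labelled with Cy5 on the arrays numbered 1 and 2 of each group and with Cy3 on those numbered 3 and 4. The direction of every ratio, exposed over control, therefore follows from the labels. Per the series' design text, each condition had 4 biological replicates.

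The deposited table holds 1 value per feature and sample, for 15207 numbered features, with no value missing. The authors' values were read as log2 intensities per channel: they run from 4.63 to 18.5, and no label states the base of the logarithm, so every fold below rests on this reading. Agilent Feature Extraction 9.5.1.1 and limma are named in the submitters' processing notes. Background correction and normalization are not given in the sources used here. The means of both channels differ by at most 0.0036 on every array, while array means differ from one another, so the values look scaled within arrays and not between them; the centring used is unknown beyond that. Background signals and quality marks of the spots were not used here, so a level near the low end of the scale has an unknown distance from background. The number of columns left unused was 0.

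The features carry numbers and no names. The reference table used here lists genes of this species by locus tag and accession and gives no link to the feature numbers, so no feature was named. The 21 gene lists fixed in advance could not be run for the same reason. Features are given by number only, with at most 2 rises and 2 falls per comparison.

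For each array the log2 value of the control sample was subtracted from that of the exposed sample. The differences were fitted for all 16 arrays together with limma 3.58.1 in R 4.3.3, with 1 coefficient for each of the 4 exposed groups and a dye term for each feature, which left 11 residual degrees of freedom. Variances were moderated with a trend on mean level (eBayes). All tests were two-sided, with Benjamini-Hochberg adjustment over the 15207 features and a threshold of 0.05. No feature was filtered out. The 4 comparisons with the controls and 4 contrasts between exposed groups come from this fit. Errors of log2 fold changes are standard errors of the fit for means of 4 arrays unless given as SD. They use 1 spread per feature, estimated from all 16 arrays. A feature therefore has the same error in all 4 comparisons with the controls, whatever the scatter of the arrays of a group. The number of arrays limits the precision: the median 95% confidence interval of a comparison with the controls extended 0.352 log2 units to each side, or 1.28-fold, and that of a contrast 0.498 log2 units. Tables and plots were also made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

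The features named for each comparison are the 2 largest rises and the 2 largest falls among features past the threshold, and in the comparisons with the controls only those with the same sign on all 4 arrays of the group. This rule, the tests and most alternatives were fixed before the data were examined. Features named outside the rule are marked as such.

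Whether equal numbers mark paired samples was checked on the residuals of the fit. Within each exposure type, the NOEC and EC50 arrays of the same number deviated together, with correlations across features of 0.48, 0.19, 0.47 and 0.44 for the extract and 0.50, 0.18, 0.19 and 0.39 for the soil. Across exposure types the same-numbered arrays did not, with correlations from -0.24 to 0.039. The fit has a common dye term, so a dye effect that differs between types raises the first correlations and lowers the second. With a dye term for each type, the estimated within-number correlation was 0.362 for the extract and 0.22 for the soil. It was 0.428 with the common term. The pairing is read from the data, within exposure types only, and the labels do not state it. Fits with the replicate number as a block are given where they change a count by over 1.5 times.

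The fit was tested on simulated log ratios with the spread of the real features in each exposure type and 200 changed features. For extract EC50 against its control, with 15207 features, it recovered 42% of the features changed 1.5-fold, 90% at 2-fold, 96% at 4-fold and 100% at 8-fold. The corresponding shares for soil EC50 were 46%, 80%, 96% and 98%. False calls made up 4.76% of the calls for soil EC50 and 27.8% for extract EC50, where the wider spread of the extract arrays is averaged with the narrower spread of the soil arrays; with the 8 arrays of the exposure type alone the share was 4.58% for extract EC50 and 7.14% for soil EC50. When as many changes as were called in the data were planted, the false share was 7.33% for extract NOEC and 7.23% for extract EC50. The planted changes were the fitted ones of the called features, with all others unchanged, in a single draw of independent features. These shares are not the error rates of the real lists. Counts from the 8 arrays of the exposure type alone are therefore given beside the extract counts.

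The alternatives were the model without dye term, all samples fitted separately without or with the array as a block, the 8 arrays of the exposure type alone, median centring, quantile and loess normalization, leaving out the dimmest 25% of features, a replicate block, array weights, a 2-fold minimum, and leaving out each array in turn. Averaging of probes of 1 gene and an offset of 50 for linear intensities were also planned and were not run, because no table pairs features with genes and the values are already logarithmic. A replicate block within the exposure type, leaving out soil EC50 array 3 from every count, and disjoint sets of arrays that share no control number were added after the data were seen.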

Results

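The study measured how the transcriptome of Folsomia candida responded to soil from a landfill and to an extract of that soil, each at a low and a high concentration. Extract NOEC, extract EC50, soil NOEC and soil EC50 had 4 exposed samples each, and the acetone and LUFA controls had 8 samples each. Every exposed sample shared its array with 1 control sample, and 15207 features were compared on each of the 16 arrays.

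The median log2 intensities of the exposed samples on arrays 1 to 4 were 9.05, 8.97, 8.84 and 8.55 for extract NOEC and 9.08, 9.08, 8.86 and 8.93 for extract EC50. They were 6.84, 7.43, 7.54 and 7.50 for soil NOEC and 7.42, 7.76, 8.81 and 7.54 for soil EC50. The control samples on the same arrays had medians of 9.05, 9.02, 8.79 and 8.56 beside extract NOEC and 9.11, 9.06, 8.89 and 8.92 beside extract EC50. Those beside soil NOEC were 6.86, 7.40, 7.54 and 7.51, and those beside soil EC50 were 7.43, 7.77, 8.82 and 7.56. The extract arrays were brighter than the soil arrays, with a mean array median of 8.94 ± 0.18 against 7.61 ± 0.56 (SD, n = 8 arrays each, exact permutation test, two-sided p = 0.00047). Log ratios of exposed to control sample also spread more widely on the extract arrays, with an SD across features of 1.03 ± 0.12 against 0.527 ± 0.087 (SD, n = 8, exact permutation test, two-sided p = 0.00016). Both permutation tests treat the 8 arrays of a type as independent. Arrays of equal number may share control RNA, so these p-values may be too small. The array sets follow the exposure type, so a difference between array sets and a difference between exposure types cannot be told apart by level alone.

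**Figure D1:**
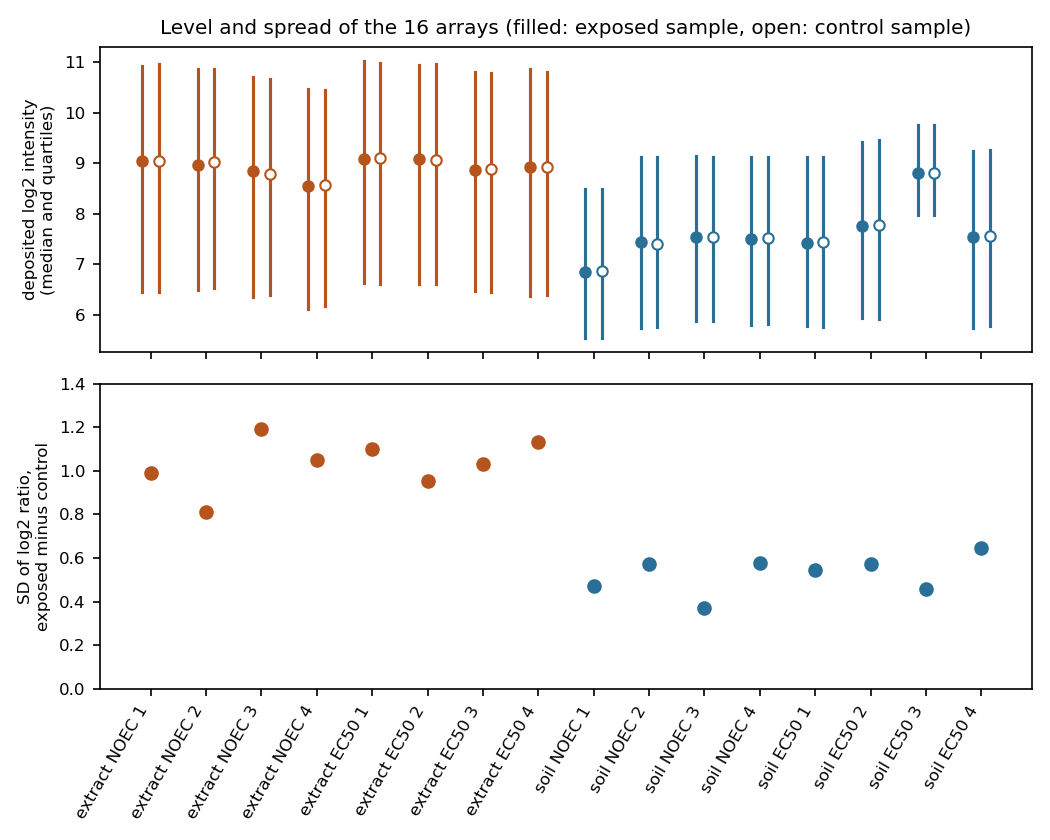
Median and quartiles of the deposited log2 intensities of the exposed and control sample of each array (top), and the SD across 15207 features of the log2 ratio of exposed to control sample (bottom, log2 units). The SD lies between 0.813 and 1.19 on the 8 extract arrays and between 0.372 and 0.648 on the 8 soil arrays.

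At the NOEC, the extract changed the level of 5890 of 15207 features (38.7%) relative to the acetone control, with 3568 higher and 2322 lower. Most changes were small, with a median size of 0.783 log2 units (1.72-fold). Large changes were mostly falls: 28 features were at least 8-fold higher and 180 at least 8-fold lower. The largest rises were those of feature 2902, by 4.78 ± 0.76 log2 units (27.4-fold, adjusted p = 0.00032), and feature 12629, by 4.73 ± 0.73 (26.5-fold, adjusted p = 0.00025). Feature 7424 fell by 8.92 ± 1.3 log2 units (486-fold, adjusted p = 0.00014), from 14.96 ± 0.63 in the controls to 6.04 ± 0.15 in the exposed samples (SD, n = 4 arrays, limma). Feature 7979 fell by 8.59 ± 1.2 (384-fold, adjusted p = 0.00014), and all 4 of these features moved in the same direction on 4 of 4 arrays. The exposed levels of features 7424 and 7979 lie close to or below the lower quartile of these samples, 6.12 to 6.49, where the distance from background is unknown, so both folds depend on the low end of the scale. The rises have this limit on the arrays with the largest ratios: the control level was 6.32 and 6.18 for feature 2902 on arrays 3 and 4 and 5.98 for feature 12629 on array 4, where the lower quartiles of the control samples were 6.38 and 6.16. The fit of the 8 extract arrays alone called 4959 features. The split between higher and lower calls depended on the scaling: loess of each array's ratios on level gave 2681 higher and 2925 lower.

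At the EC50, the extract changed 5746 features (37.8%), 3227 higher and 2519 lower, with a median size of 0.807 log2 units (1.75-fold). At least 8-fold changes comprised 73 rises and 183 falls. Feature 11911 rose by 6.38 ± 0.41 log2 units (83.3-fold, adjusted p = 1.4e-07), from 10.08 ± 0.24 to 16.46 ± 0.26 (SD, n = 4 arrays, limma), and feature 11804 rose by 6.33 ± 0.35 (80.7-fold, adjusted p = 4.3e-08). Feature 1022 fell by 7.26 ± 0.61 log2 units (154-fold, adjusted p = 1.8e-06), from 12.69 ± 1.49 to 5.43 ± 0.51 (SD, n = 4 arrays, limma). Feature 14324 fell by 6.91 ± 0.54 (120-fold, adjusted p = 8.4e-07), and the same limit of the scale applies to the folds of both falls. These 4 features were also called at the NOEC, where feature 11911 rose by 3.64 ± 0.41 (adjusted p = 3.3e-05) and feature 1022 fell by 6.94 ± 0.61 (adjusted p = 5.9e-06). With the 8 extract arrays alone, 4934 features were called. Loess scaling gave 2403 higher and 3049 lower calls at the EC50.

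**Figure D2:**
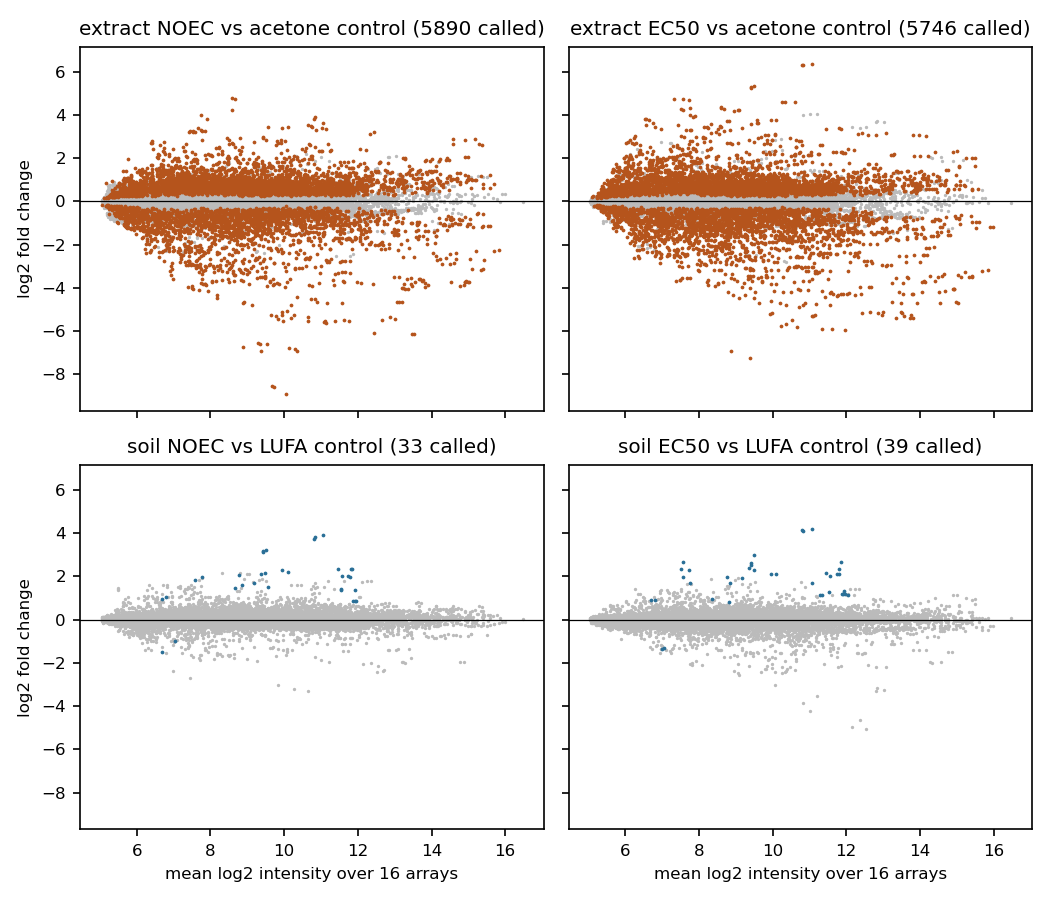
Log2 fold change against mean log2 intensity over 16 arrays for 15207 features in each comparison with the controls. Coloured points are features past the adjusted threshold: 5890 and 5746 for the extract, 33 and 39 for the soil.

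Whole landfill soil at the NOEC changed 33 features relative to LUFA soil, 31 higher and 2 lower. At an unadjusted p under 0.05 (limma), 546 features were higher and 605 lower, so this balance holds for the called features only. The called changes had a median size of 1.99 log2 units (3.96-fold), and 28 of the 33 features changed at least 2-fold. With few calls mainly large changes pass the adjusted threshold, so this median does not compare with that of the extract. Over all features the SD of log2 fold changes was 0.308 in soil NOEC and 0.85 in extract NOEC. Feature 11911 rose by 3.90 ± 0.41 log2 units (14.9-fold, adjusted p = 0.00022), from 7.31 ± 0.85 to 11.21 ± 0.74, and feature 5024 rose by 3.83 ± 0.34 (14.2-fold, adjusted p = 5.7e-05; SD of levels and n = 4 arrays, limma). The 2 falls were those of feature 41, by 1.52 ± 0.25 log2 units (adjusted p = 0.018), and feature 561, by 0.98 ± 0.18 (adjusted p = 0.039). The exposed level of feature 561 was 6.03 ± 0.04 (SD, n = 4 arrays), beside lower quartiles of 5.54 to 5.87 in these samples. The size of this fall therefore also depends on the low end of the scale. Neither fall kept its call in every alternative: without soil NOEC array 1, 2 or 3 both were lost, and feature 561 was also lost without array 4. A random replicate block within the exposure type, the pairing seen in the data, gave 27 features, 27 higher and 0 lower (limma), with adjusted p = 0.054 for feature 41 and 0.10 for feature 561. A replicate block over all numbers, which also joins arrays of different exposure types that do not deviate together, gave 51 (39 higher, 12 lower), the array as a random block 158 (96 higher, 62 lower) and no array block 19, all higher.

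At the EC50, whole soil changed 39 features, 37 higher and 2 lower, with a median of 1.98 log2 units (3.94-fold). Of the features with an unadjusted p under 0.05 (limma), 850 were higher and 497 lower. Feature 11911 again had the largest rise, by 4.22 ± 0.41 log2 units (18.6-fold, adjusted p = 9.5e-05), from 7.93 ± 0.90 to 12.15 ± 0.34 (SD, n = 4 arrays, limma). Feature 11804 rose by 4.15 ± 0.35 (17.8-fold, adjusted p = 1.9e-05). Feature 14787 fell by 1.35 ± 0.20 log2 units (adjusted p = 0.0048) and feature 12943 by 1.31 ± 0.23 (adjusted p = 0.033), and both calls were lost without array 1 or array 2, that of feature 12943 also without array 4 and with a random replicate block within the exposure type (adjusted p = 0.084). Their exposed levels, 6.19 ± 0.74 and 6.14 ± 0.82 (SD, n = 4 arrays), also lay near the low end of the scale. On array 3 the interquartile range of levels was 1.75 log2 units, against 3.31 to 3.49 on the other 3 arrays of the group, and leaving it out gave 33 features. The count was 24 without array 1 and 24 without array 4. The balance of higher and lower calls also moved with the setting: 43 higher and 17 lower with the 8 soil arrays alone (60 in all), 57 and 7 after quantile normalization (64), 210 and 51 with the array as a random block (261), and 244 and 156 with array weights (400).

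**Figure D3:**
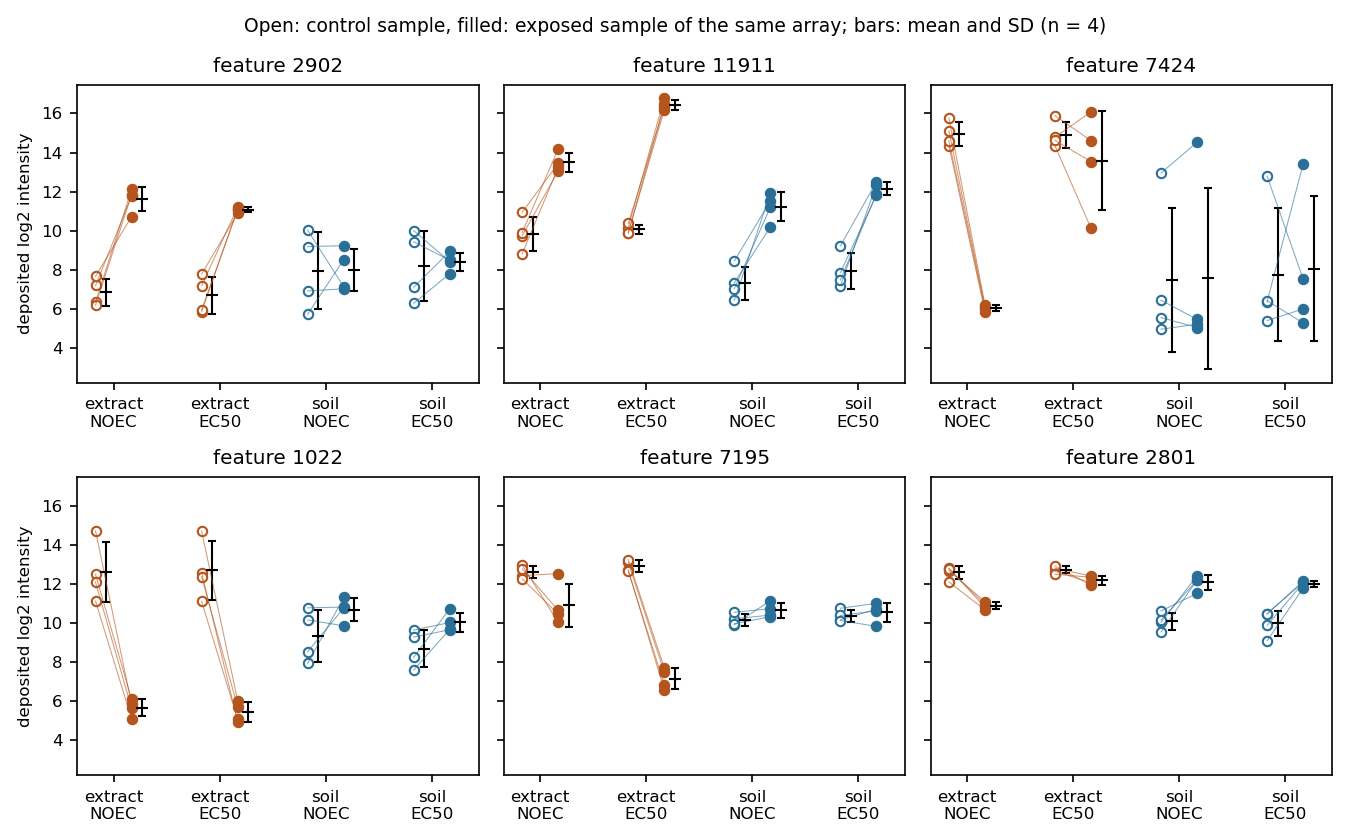
Deposited log2 intensity of 6 features in each control sample (open) and exposed sample (filled), with lines joining the samples of 1 array and bars giving mean and SD (n = 4). Feature 11911 is higher in every exposed sample than in its control, feature 1022 lies near the low end of the scale in all 8 extract-exposed samples, and feature 7424 differs widely between jars within the soil groups.

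The contrast of the extract concentrations asks which features responded differently at the EC50 than at the NOEC. It called 387 features, 204 with a more positive and 183 with a more negative effect at the EC50. With NOEC and EC50 arrays of equal number paired by a replicate block, 1463 features were called, 647 more positive and 816 more negative, including 386 of the 387. That block also takes up a dye effect of each exposure type, so the rise cannot be credited to the pairing alone. Feature 7195 had a more negative effect at the EC50 by 4.09 log2 units: it fell by 5.79 ± 0.33 there and by 1.70 ± 0.33 at the NOEC (adjusted p of the contrast 0.00073, limma). The effects on feature 13554 were -5.76 ± 0.35 at the EC50 and -1.79 ± 0.35 at the NOEC (adjusted p of the contrast 0.0012). Feature 7424 differed in the other direction by 7.60 ± 1.8 log2 units (adjusted p = 0.041), since its ratios at the EC50 ran from -4.23 to 1.30 over 4 arrays (mean -1.32, adjusted p = 0.44). Feature 14930 differed by 7.16 ± 1.7 (adjusted p = 0.045), and the contrasts of features 7424 and 14930 lost their calls without any of 7 of the 8 extract arrays. The 8 extract arrays alone gave 102, of which 84 were more positive and 18 more negative, and quantile normalization gave 133. The count was 202, 188 and 251 without extract NOEC array 1, 2 or 4, and 149, 697 and 154 without extract EC50 array 1, 3 or 4.

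For whole soil, no feature passed the threshold in the contrast of EC50 and NOEC (0 of 15207, limma), and 1003 features had an unadjusted p under 0.05. The smallest adjusted p was 0.68. Feature 11911, which rose at both concentrations, had effects of 3.90 ± 0.41 and 4.22 ± 0.41. Pairing the arrays by a replicate block within the exposure type also gave 0 features. With no array block 1995 features were called, 1915 of them more positive at the EC50, a setting in which differences between arrays stay in the values.

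The contrasts between exposure types ask whether the effect of the extract differs from that of the whole soil. At the NOEC, 4134 features differed (27.2%), 2482 with a more positive and 1652 with a more negative effect of the extract. Features 2902 and 12629 had effects that were more positive by 4.76 ± 1.1 and 4.68 ± 1.0 log2 units (adjusted p = 0.0064 and 0.0057), and features 7424 and 7979 effects that differed by -9.01 ± 1.8 and -8.77 ± 1.7 (adjusted p = 0.0032 and 0.0029). In soil NOEC feature 2902 had a mean effect of 0.01 ± 0.76, but its ratios on arrays 1 to 4 were 2.80, 0.11, 0.04 and -2.90. Feature 7424 had one of 0.08 ± 1.3, and its LUFA controls lay at 4.95, 5.55, 12.95 and 6.44, with the lowest value in the table at 4.63. A fall as large as that with the extract therefore had no room on soil arrays 1, 2 and 4. On array 3, which had room, the ratios were 1.58 for feature 7424 and 1.54 for feature 7979. In soil EC50, array 3 also had room, with LUFA controls at 12.79 for feature 7424 and 12.38 for feature 7979. The ratios there were -5.27 and -4.77. The signs were opposite on these arrays, 1 at each concentration. The contrasts of features 7424 and 7979 therefore do not tell whether the soil would lower them. At the EC50, 2314 features differed (15.2%), 1032 more positive and 1282 more negative. Features 1022 and 14324 had effects that differed by -8.60 ± 0.87 and -8.13 ± 0.76 (adjusted p = 6.2e-05 and 3.3e-05): both fell with the extract, and their effects in soil EC50 were 1.34 ± 0.61 and 1.22 ± 0.54 (adjusted p = 0.56 and 0.54), positive on all 4 arrays, from LUFA controls that for feature 1022 lay at 7.59 to 9.63 and left less room for a fall than the acetone controls. Features 7678 and 15286 differed by 8.49 ± 2.7 and 8.40 ± 2.6 (adjusted p = 0.045 and 0.041), although neither was called against its control in any exposure, and both lost the call without any of extract EC50 arrays 1 and 4 and soil EC50 arrays 2, 3 and 4. Loess scaling gave 1504 higher and 2069 lower calls at the NOEC and 810 higher and 1548 lower at the EC50, and without soil NOEC array 4 the NOEC count was 2417.

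Features that changed at both extract concentrations mostly moved in the same direction. In all 2263 features were higher at both, where independent lists of these sizes would share 757, and 1495 were lower at both, where such lists would share 385; 55 were called in opposite directions. The fold changes correlated across features with r = 0.710 (Spearman 0.701), and features are not independent replicates. The control samples of equal number were alike between both sets of arrays, so part of this overlap may come from shared controls: unchanged groups simulated with the spread and the within-number correlation of the extract arrays (0.362) gave r = 0.359 and a covariance of 0.0279, against an observed covariance of 0.539. Arrays of different numbers, which share no control, gave a mean r of 0.602 and a covariance of 0.505. Here each concentration was a mean of 2 arrays without a dye term, so noise alone would lower r. For the soil, 28 features were higher at both concentrations, against 0.0754 for independent lists, a number that leaves out the controls shared by equal-numbered arrays. Over all features r was 0.361 with a covariance of 0.0383 for the soil. Spearman was -0.028, and 46.5% of features had the same sign, so the ranks showed no positive relation. Unchanged groups simulated with the soil arrays' spread gave r = 0.215 and a covariance of 0.0105. The soil arrays of different numbers gave r from -0.0815 to 0.557 (mean 0.146) and a mean covariance of 0.0204, so a relation over all features did not hold for every choice of arrays.

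A group of 23 features was called higher in all 4 exposures, and 0 features were called lower in all 4 (limma). The 0 does not exclude shared falls: feature 561 had effects of -1.32 and -1.79 in extract NOEC and EC50 and -0.98 and -0.87 in soil NOEC and EC50 (adjusted p = 0.00011, 6.5e-06, 0.039 and 0.08). Feature 14787 had -1.35, -1.85, -0.90 and -1.35 in the same order (adjusted p = 0.00017, 1.1e-05, 0.13 and 0.0048). Features 561 and 14787 lay in the same set of near-identical profiles, described in the last part, so they do not count as separate cases. The median rise of these 23 was 2.52 log2 units in extract NOEC, 3.41 in extract EC50, 2.15 in soil NOEC and 2.16 in soil EC50. Features 11911, 11804 and 5024, which also formed such a set, belonged to this group, and in extract EC50 feature 5024 rose by 6.32 ± 0.34 (adjusted p = 4.3e-08). Of the 44 features called in either soil exposure, 31 were higher in both extract exposures. Across all features, the mean extract and soil effects correlated with r = 0.106 at the EC50 and -0.021 at the NOEC (Spearman 0.260 and -0.191), while single soil arrays correlated with the mean extract EC50 ratio at -0.36 to 0.48. A set of 3 features, chosen after their values were seen, was higher in both soil exposures and lower in extract NOEC. Their log ratios differed by at most 0.25 on any of the 16 arrays, so they do not count as 3 separate findings. Feature 2801 rose by 2.01 ± 0.24 in soil NOEC (adjusted p = 0.00059) and by 2.03 ± 0.24 in soil EC50 (adjusted p = 0.00043) and fell by 1.71 ± 0.24 in extract NOEC (adjusted p = 0.00013). Features 9777 and 10812 fell by 1.69 ± 0.21 and 1.72 ± 0.21 in extract NOEC (adjusted p = 6.0e-05 and 4.9e-05) and rose by 2.01 ± 0.21 and 1.99 ± 0.21 in soil NOEC (adjusted p = 0.00022 for both). In extract EC50 their effects were -0.53, -0.55 and -0.56 for features 2801, 9777 and 10812 (adjusted p = 0.094, 0.051 and 0.048, limma). The contrast with extract NOEC depended on the replicate block, which also takes up a dye effect of each type. It gave 1.18 ± 0.33, 1.14 ± 0.30 and 1.16 ± 0.29 without a replicate block (adjusted p = 0.078, 0.058 and 0.053), and adjusted p = 0.010, 0.011 and 0.011 with equal numbers paired by a fixed block within the exposure type, a fit chosen after the data were seen. The extract EC50 calls depended on the scaling: loess gave adjusted p = 0.038, 0.016 and 0.014, median centring 0.062, 0.033 and 0.030, and quantile normalization 0.18, 0.12 and 0.11.

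**Figure D4:**
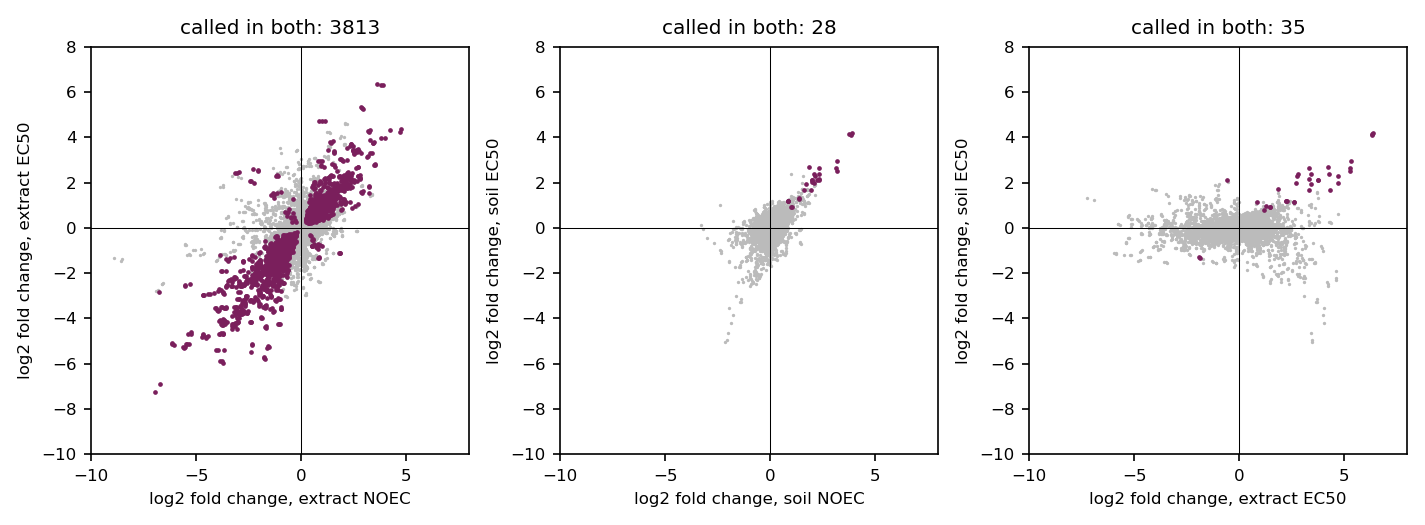
Log2 fold changes of 15207 features in extract EC50 against extract NOEC, soil EC50 against soil NOEC, and soil EC50 against extract EC50. Dark points are features called in both exposures; those of the extract lie along the diagonal (r = 0.710 over all features), and most of those shared by extract and soil are rises.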

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

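The test of the spread between arrays and the comparison of control with exposed samples of equal number were chosen after the results they bear on were seen.

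The effects of extract and whole soil differed for 4134 features at the NOEC and for 2314 at the EC50, by a test of the difference itself. Of the 35 splits of the 8 arrays compared, 1 gave as many calls at each concentration, the real one. The highest other split gave 5 and 0. A share of 1 in 35 is under 0.05 and the smallest these splits can give. The other splits mix extract and soil arrays, so the extract effect adds to their spread and lowers their counts. A difference between the array sets, which follow the exposure type, would give the same outcome. Dimmer soil arrays as the whole cause were examined among the 2183 features with a mean level of at least 10 on the soil arrays. The share called was 0.687% for soil EC50 and 53.1% for extract EC50, a ratio of 0.013. The adjusted threshold depends on the calls among all features, so this ratio partly restates the difference in counts and cannot decide. Without a threshold, the SD of log2 fold changes was 0.447 and 1.33 in these bright features and 0.344 and 0.894 over all features. The gap did not close among bright features, which argues against dimness as the whole cause. A wider absolute spread between soil arrays is argued against as well, since their median residual SD was 0.72 times that of the extract arrays. Compressed ratios would shrink this SD too, so a spread that is wider relative to the changes stays open. Acetone control jars that were themselves out of place stay open: LUFA minus acetone control levels had a slope of 0.18 on the extract effect taken from other arrays, against 0.75 for extract-exposed minus acetone control levels, and the slope compares array sets that also differ in level. A difference in what the animals took up from extract and soil is a possible biological explanation. Uptake was not among the values used here, and this explanation was not tested.

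The NOEC and EC50 arrays of equal number deviated together within each exposure type. A control RNA extract shared by both arrays is a candidate explanation that the values bear out: the deviations of the control samples correlated at 0.33 to 0.88, those of the exposed samples at -0.079 to 0.12, and the smallest of the 4 differences was 0.21. A batch shared by exposed and control jars of equal number would raise the correlations of the exposed samples as well, and these stayed near 0. The labels do not say whether control RNA was used on more than 1 array, so the 8 control samples of each type may stand for fewer jars.

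The effects of both extract concentrations differed for 387 features. Of the 35 splits of the 8 extract arrays, 2 gave as many calls, the real one and the split by dye, numbers 1 and 2 against 3 and 4, with 887. By this share chance is not excluded, but the rival split is a factor of the design, and the highest of the remaining 33 splits gave 52. Each fit held a dye term common to extract and soil arrays, and in this split only the soil arrays set it. The 887 calls therefore go with a dye effect that differs between exposure types. Anything else that parts numbers 1 and 2 from 3 and 4 could also give them. They do not go with the pairing alone, since the other 2 splits that part no equal-numbered pair gave 0. Among the 8 splits that part all 4 pairs the real one gave 387 and the highest other 1, but these splits are too few for a share under 0.05. For soil EC50 against soil NOEC the real count was 0, so all 35 splits give as many by construction. The count of splits therefore decides nothing here. The split by dye gave 910, a test of the same difference between exposure types, and the highest other gave 3. The fit with the replicate number as a block gave 1463 for the extract and 0 for the soil. Within exposure types this block also takes up a dye effect of each type, so the rise from 387 cannot be credited to the pairing alone.

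For the comparisons with the controls, only 8 splits part the samples of each array, too few for a share under 0.05. In each comparison 1 of the 8 gave as many calls, the real one. The real and the highest other counts were 5890 and 19 for extract NOEC, 5746 and 3 for extract EC50, 33 and 0 for soil NOEC, and 39 and 0 for soil EC50.

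Of 36 groups tested for a sample far from the rest, 4 had one, where chance gives about 1 in 20 groups, or 1.8. The groups are not independent, and all but 1 of the 4 concern soil EC50 array 3 or its control. The 4 therefore do not show an excess over chance. The interquartile range of soil EC50 array 3 was 1.75, against 3.31 to 3.49 on the other arrays of its group. Its control sample had a median level of 8.82, against 6.86 to 7.77 in the other LUFA controls, and an interquartile range of 1.77 against 2.96 to 3.55. In the dimmest 10% of features the exposed sample lay 2.35 and the control 2.51 log2 units above the other soil arrays, and in the brightest 10% 0.277 and 0.222. The exposed sample of soil NOEC array 1 had a median level of 6.84, against 7.43 to 7.54 in the other 3.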

How the results depend on the processing

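The replicate block within exposure types, the disjoint arrays and leaving out soil EC50 array 3 from every count were chosen after the data were seen. With all samples fitted separately and no array block, counts were 2710 and 3084 for extract NOEC and EC50, 19 for soil NOEC, 596 and 1995 for the extract and soil dose contrasts, and 1236 and 1562 for extract against soil at the EC50 and NOEC. This setting leaves differences between arrays in the values. With the array as a random block they were 158 and 261 for soil NOEC and EC50, and 1400 and 1 for the extract and soil dose contrasts. A 2-fold minimum left 1961 and 2151 features for extract NOEC and EC50, and 1457 and 2052 for extract against soil at the EC50 and NOEC, by construction.

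The 8 arrays of the type alone gave 60 for soil EC50 and 102 for the extract dose contrast, quantile normalization 64 and 133, and array weights 400 for soil EC50; the cause was not tested. The replicate block over all numbers, pairs across types included, gave 51 for soil NOEC. Paired within exposure types, the replicate block gave 1463 (fixed) and 1747 (random) for the extract dose contrast. The fixed block was run for the dose contrasts only and also takes up a dye effect of each type. The random block changed no other count by over 1.5 times. Leaving out 1 array gave 4392 to 5715 for extract NOEC, 4104 to 5594 for extract EC50, 22 to 33 for soil NOEC, 24 to 33 for soil EC50, 149 to 697 for the extract dose contrast, 0 to 0 for the soil dose contrast, 1543 to 2203 for extract against soil at the EC50 and 2417 to 4388 at the NOEC. The other alternatives kept every count within 1.5 times.

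The correlation of fold changes between concentrations was 0.602 for the extract and 0.146 for the soil with no shared control number. These values use means of 2 arrays per concentration without a dye term, so noise alone would lower them. Among the 44 features called in either soil exposure r was 0.933, a value raised by choosing features on these same fold changes. The correlation of extract and soil effects at the NOEC changed sign, from -0.021 to 0.0149, among called features. For the 28 values of named features, 484 alternatives gave 425 values on the same side of the threshold, 59 that lost the call and 0 with another sign; the losses were the 4 soil falls and features 7424, 14930, 7678 and 15286 in contrasts. Background signals were not used here, so a limit from signal over background was not set.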

Other observations

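The tests in this part were all chosen after the results were seen.

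Some features differed widely between jars of the same control. In the acetone controls 44 features, and in the LUFA controls 67, spanned at least 6 log2 units (64-fold) over the 8 samples, and 11 of these did so in both. Among the exposed groups, the number with such a span over 4 samples was 28 in extract NOEC, 43 in extract EC50, 59 in soil NOEC and 34 in soil EC50. Feature 7678 lay at 5.06 and 5.10 in the LUFA controls of number 1 and at 14.82 and 15.06 in those of number 2. The control samples of equal number nearly matched in these features, with a median gap of 0.312 log2 units in the acetone and 0.257 in the LUFA controls, against 2.85 and 3.40 for controls of different numbers. For the exposed samples of equal number the gap was 1.71 with the extract and 2.95 with the soil. Feature 7424, at 14.35 to 15.89 in all acetone controls and 5.85 to 6.21 in all extract NOEC samples, was among the wide features of the LUFA controls, where its level ran from 4.95 to 12.95.

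A part of the features fall into sets of 3 with near-identical profiles, which may be repeat spots of 1 probe. Over all samples 883 sets of 3 were each other's nearest neighbours, and also 3787 sets of 2 and 32 sets of 4, so most features lay in no closed set of 3. Of 1126 such sets found in the extract and 358 in the soil samples, 155 were found in both. The 358 sets hold 1074 of the 15207 features, and 211 of them held a feature called for extract EC50. In 60.7% of these all 3 were called in the same direction, against 2.18% of sets matched on level. Separate transcripts with alike profiles would give the same outcome, so this share does not tell them from repeats. Calls in opposite directions occurred in 5 sets, against 78 of the matched ones, so not every set behaved as repeats of 1 probe. The median SD of log ratios within a set was 0.193 on the extract arrays, against 0.576 between arrays of a group. Of the 33 features called for soil NOEC, 24 lay in 9 sets found in the extract samples, and of the 39 for soil EC50, 29 lay in 12 sets. Among the sets found over all samples, features 5024, 11804 and 11911 formed a set, as did features 561, 12943 and 14787, features 7424, 7979 and 14930, and features 2801, 9777 and 10812. Feature 2902 shared a set with feature 12629, feature 7195 with feature 13554 and feature 7678 with feature 15286. Features of such a set that are named as separate rises or falls may therefore be repeats of 1 probe, and the counts of changed features may overstate the number of separate transcripts.

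The soil arrays lay at different places along the direction of the extract response. The correlation of their log ratios with the mean extract EC50 ratio, across features, was 0.27, -0.28, 0.053 and -0.36 for soil NOEC arrays 1 to 4 and 0.48, 0.08, -0.03 and -0.23 for soil EC50 arrays 1 to 4. Arrays of equal number had alike control samples, so a like order at both concentrations is no independent repeat. The directions of all ratios follow from the dyes in the labels.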
